A study of Mus musculus with 12 samples.

How the data were processed

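Polyadenylated RNA was sequenced from 12 mouse heart libraries, 4 from wild-type mice after sham surgery (Sham WT), 4 from wild-type mice after transverse aortic constriction (TAC WT) and 4 from mice lacking the long noncoding RNA Nron after the same constriction (TAC KO). Per the labels, hearts were taken 6 weeks after surgery and libraries were made from 250 ng of RNA. No sham-operated knockout group was analysed here. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples. Replicates were numbered in the order of their accessions.

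The deposited values were counts: raw whole-number counts per gene, with 1 file per library and 54146 gene records in each. The submitters' processing notes name FastQC 0.11.8, Trim Galore 0.5.0, STAR, featureCounts 1.6.4, StringTie 1.3.5, MultiQC 1.7, bcl2fastq and DESeq2, and the genome build GRCm38. The role and settings of each tool, the annotation release and the strand setting were not given in the sources used here. Gene identifiers were matched without their version suffix to the mouse reference annotation, which named 54079 of the records and left 67 without a symbol.

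Library totals ranged from 26288519 to 35945770 counts. A gene with 0 counts in a library was given an upper limit of 3 counts, which was 0.083 to 0.114 counts-per-million (CPM) across the libraries. Counting intervals for ratios were exact at the 95% level. Intervals and limits cover counting error only, since reads without molecular identifiers are not independent molecules.

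Differential expression was tested in R 4.3.3 with edgeR 4.0.16, using the quasi-likelihood F-test on raw counts, TMM scaling and the filterByExpr filter with the 3 groups. All 12 libraries entered 1 fit, which tested 15477 genes. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, computed over all tested genes in each comparison. The common biological coefficient of variation was 0.113. Fold changes are given as log2 values with the standard error (SE) of the fit, and group levels as mean CPM with the standard deviation (SD) of 4 libraries.

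Before the data were examined, 32 lists of genes were fixed for pathways of the heart, cell types and RNA quality, and 31 had at least 3 tested members. They were tested with camera in limma 3.58.1, which compares a list with all other tested genes, at a preset inter-gene correlation of 0.01. The same test was run with a correlation estimated from the data. The fry test asks whether a list's genes move, on balance, in 1 direction and makes no comparison with other genes. Adjusted p-values for lists were computed over the 31 lists. Members were counted as changed over all tested genes and again adjusted over the list alone.

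A naming rule was fixed before the data were examined. It took up to 10 genes with the highest and up to 10 with the lowest fold change, or up to 5 and 5 for TAC KO versus Sham WT. These had to pass the threshold, reach a mean of 1 CPM, carry an established symbol and show no overlap between the groups' CPM ranges. It added up to 4 members of each list by smallest p, a fixed set of stress, calcium and matrix genes, and the protein-coding genes within 500 kb of Nron that passed. The rule allowed 425 gene and comparison pairs. The 150 pairs examined one by one under every alternative were chosen after their values were seen. They include 6 outside the rule, which are Malat1, Neat1, Gm15772, Gdpd3, Gm4735 and E330017L17Rik in TAC KO versus TAC WT, and the others were taken from the 425. Some genes that the rule allowed are not reported here.

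Because TAC WT enters both of the fold changes compared in the overlap of the TAC and knockout effects, the overlap was set beside 20 simulations that kept the TAC effect and set the knockout equal to TAC WT. It was also recomputed in 6 splits in which 2 TAC WT libraries chose the genes and the other libraries of that group gave the knockout effect. Trends of each library with GC content and transcript length were fitted as splines with 5 degrees of freedom and removed as offsets. This last step was chosen after the data were examined. Near-identical copies of transcripts were searched with minimap2 2.31-r1302 at 95% identity or more over at least 50% of the length.

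The alternatives were DESeq2 1.42.0, limma voom with quality weights, RLE and upper-quartile scaling, no low-count filter, a filter of 1 CPM in 4 libraries, fits of the compared groups alone, 1 surrogate variable from sva 3.50.0, a 1.5-fold minimum and the removal of each library in turn. The tests were also run on simulated data, in which 200 of 15477 genes were changed. In these, edgeR recovered 74 to 86% of the genes changed by 2-fold and 54 to 58% of those changed by 1.5-fold, and 5.37 to 7.79% of its calls were false. DESeq2 gave 11.04 to 15% false calls in the same data. With a simulated GC trend, false calls numbered 7181 without the offsets and 10 with them. The simulated trend was steeper than the one in the data, and no length trend was simulated. It was a smooth function of GC content, which the offsets are built to remove, so these numbers check the procedure only. Figures and tables were made with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.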

Results

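Gene expression was measured by sequencing polyadenylated RNA from 12 mouse heart samples in 3 groups of 4 libraries. Transverse aortic constriction (TAC) narrows the aorta by surgery and loads the left ventricle with pressure, and sham surgery leaves the aorta open. Wild-type mice had sham surgery (Sham WT) or TAC (TAC WT), and mice lacking the long noncoding RNA Nron had TAC (TAC KO), all 6 weeks before the hearts were taken. Totals were 27596898 to 35491024 counts in Sham WT, 26288519 to 35945770 in TAC WT and 28565856 to 35777820 in TAC KO. Between 21642 and 22597 genes had a count in each library. Mitochondrially encoded genes took 21.5% ± 0.91 of counts in Sham WT, 18.5% ± 1.21 in TAC WT and 19.6% ± 1.28 in TAC KO (SD, n = 4).

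The 3 groups separated on the first principal components, which held 29.0% and 25.6% of the variance. Correlations of log2 CPM across genes ran from 0.987 to 0.994 between libraries of a group and from 0.972 to 0.985 between libraries of different groups. Genes are not independent replicates in these values.

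**Figure D1:**
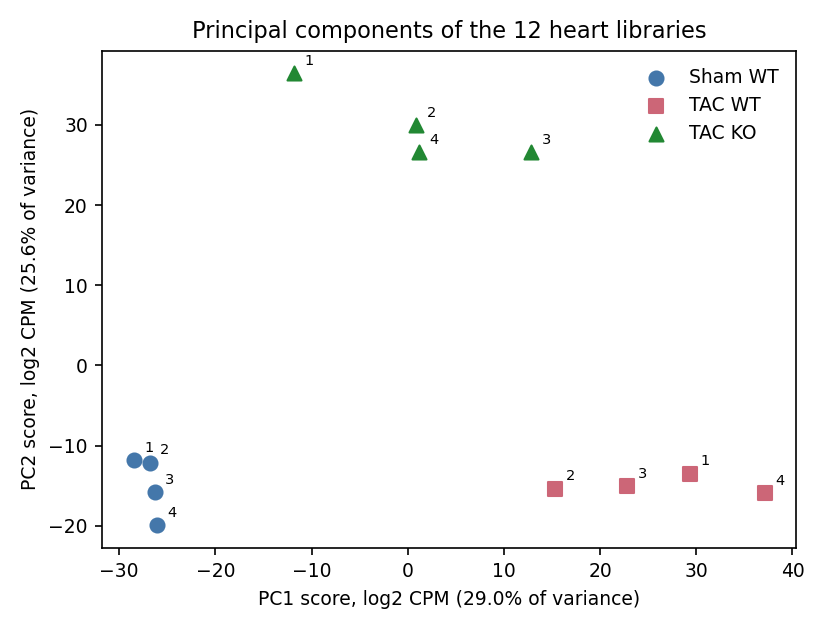
Scores of the 12 libraries on the first principal components of log2 CPM, with replicate numbers beside the points. The first component, 29.0% of the variance, ran from Sham WT to TAC WT, and the second, 25.6%, set the 4 TAC KO libraries apart from all wild-type libraries.

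The comparison of TAC WT with Sham WT asked which genes pressure overload changed in wild-type hearts. Nppa, which encodes atrial natriuretic peptide, rose from 399 ± 93.2 to 3639 ± 823 CPM (SD, n = 4), a log2 change of 3.19 (SE 0.18, edgeR adjusted p = 2.096e-07). It lies on chromosome 4 from 148000722 to 148002079 of GRCm38 (ENSMUSG00000041616.9). Skeletal actin Acta1 rose from 483 ± 157 to 7259 ± 1376 CPM, and Myh7, the slow myosin heavy chain on chromosome 14 from 54970684 to 54994626, rose from 342 ± 40.7 to 2265 ± 972 CPM. The connective tissue growth factor gene Ccn2 rose by 2.69 on the log2 scale, while the fatty acid transporter Slc27a1 fell by 0.87 and the mitochondrial thiolase Acaa2 fell by 0.66. In all, 3051 of 15477 tested genes changed, 1496 up and 1555 down, of which 1248 changed by 1.5-fold or more.

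Among genes with an established symbol, a mean of at least 1 CPM and no overlap between groups, the highest named fold changes belonged to Sprr1a (log2 4.62, SE 0.96), Syndig1 (4.49), Serpinb1c (3.98), Ankrd2 (3.94, SE 0.97), Acta1 (3.91), Gdf15 (3.53), Lrp8 (3.44), Hspa1a (3.28) and the nicotinamide riboside kinase Nmrk2 (3.24). The lowest belonged to the sodium channel Scn10a (-2.62), Sbk3 (-2.60), Ankrd63 (-2.57), Cenpf (-2.50), Pdzrn4 (-2.32), Cntn2 (-2.25), Aqp4 (-2.22), Pfkfb1 (-2.19) and Angpt1 (-2.13). Adjusted p for these 18 genes ran from 3.822e-07 to 0.01107. The ranks of Sprr1a and Ankrd2 rested on TAC WT 4, at 5.66 and 14.5 CPM against at most 2.13 and 2.24 in the other TAC WT libraries, and without it their log2 changes were 3.77 and 2.40. With 1 surrogate variable Ankrd2 was at 1.49 and its call was lost (adjusted p = 0.124). Every TAC WT library lay on the same side of every Sham WT library for each of these 18 genes, as the naming rule required. Across all tested genes, 24.7% showed such separation, where chance gives 2.86%.

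Among 11 cardiac stress genes, all 11 rose, with a median log2 change of 2.55. Besides those above, Nppb rose by 2.64, Ankrd1 by 2.55, Xirp2 by 1.88 and Rcan1, a target of calcineurin signalling, by 2.39. This was the only list of 31 called with camera whose call held with an estimated correlation (adjusted p = 0.0134). Of 44 extracellular matrix genes, 35 rose and 9 did not pass, and 41 rose when adjusted over the list alone. Tgfb2 rose by 2.17, Cilp by 2.55, Postn by 2.46 and Col1a1 by 0.78. The camera call was lost with an estimated correlation (adjusted p = 0.157 with an estimated correlation). Of 14 fibroblast markers, Mgp (log2 0.92) was among 4 that rose and Scara5 (-1.28) among 2 that fell, with 5 up and 3 down adjusted over the list alone. The fibroblast call (adjusted p = 0.0484) was lost with an estimated correlation (adjusted p = 0.701 with an estimated correlation).

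Of 28 fatty acid oxidation genes, 22 fell and 6 did not pass, with 22 adjusted over the list alone. Ech1 fell by 0.66 along with Acaa2 and Slc27a1. The list was called by camera and lost with an estimated correlation (adjusted p = 0.234 with an estimated correlation). Of 43 nuclear oxidative phosphorylation genes, 17 fell and 26 did not pass, including Sdha at -0.43 among those that fell. Adjusted over the list alone, 24 fell and 1 rose, and the estimated correlation gave adjusted p = 0.701 with an estimated correlation. Of 9 tested mitochondrially encoded mRNAs, 3 fell, or 5 adjusted over the list alone, with mt-Nd5 at -0.42 (adjusted p = 0.701 with an estimated correlation). Among these mt-Co1 fell by 0.23 (adjusted p = 0.0423), a call lost on removing any of Sham WT 1 to 4, TAC WT 1 or TAC WT 4, when adjusted p ran from 0.0656 to 0.130. Of 24 contraction and calcium handling genes, 9 fell over all genes and 9 adjusted over the list alone, with 15 not passing. Kcnh2 fell by 1.03, phospholamban Pln by 0.47 and the calcium pump Atp2a2 by 0.52 (adjusted p = 0.601 with an estimated correlation). The share of counts on mitochondrial genes went from 21.5% to 18.5%, but it includes the reads of the mitochondrially encoded mRNAs and is not separate evidence.

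Of 14 heat shock genes, 11 rose, or 12 adjusted over the list alone, with Hsp90aa1 at 1.11, Hspb1 at 1.15 and Cryab at 0.73 (adjusted p = 0.105 with an estimated correlation). Of 16 immediate early genes, 7 rose, or 10 adjusted over the list alone, including Atf3 (2.21), Nr4a3 (1.55) and Myc (1.43, adjusted p = 0.234 with an estimated correlation). Both groups are also known to respond to tissue handling, and they rose in the same libraries as the stress genes. Of 25 cytokines and chemokines, 5 rose over all genes and 5 adjusted over the list alone, with Il6 at 4.51 from 0.0578 to 1.51 CPM (adjusted p = 0.741 with an estimated correlation). Il6 was at 3.82 CPM in TAC WT 4 and at most 1.07 in the other TAC WT libraries, and its log2 change was 3.55 without TAC WT 4. Osmr rose by 0.83 (adjusted p = 0.0157), a call lost without Sham WT 2 (adjusted p = 0.0533) or TAC WT 4 (adjusted p = 0.0503). Of 23 interferon-stimulated genes, 5 rose by both counts, Oas1a by 0.73 among them (adjusted p = 0.786 with an estimated correlation). Of 19 macrophage markers only Cd14 passed (log2 0.54, adjusted p = 0.0355), and none passed adjusted over the list alone. The Cd14 call was lost on removing any of Sham WT 1, 3 or 4 or TAC WT 1, 3 or 4, with adjusted p from 0.0813 to 0.0989. Its ranges overlapped between the groups. The fibroblast, mitochondrial mRNA, cytokine and interferon calls were each lost on removing at least 1 of the libraries, and a fit with 1 surrogate variable cut the number of changed genes to 1526.

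**Figure D2:**
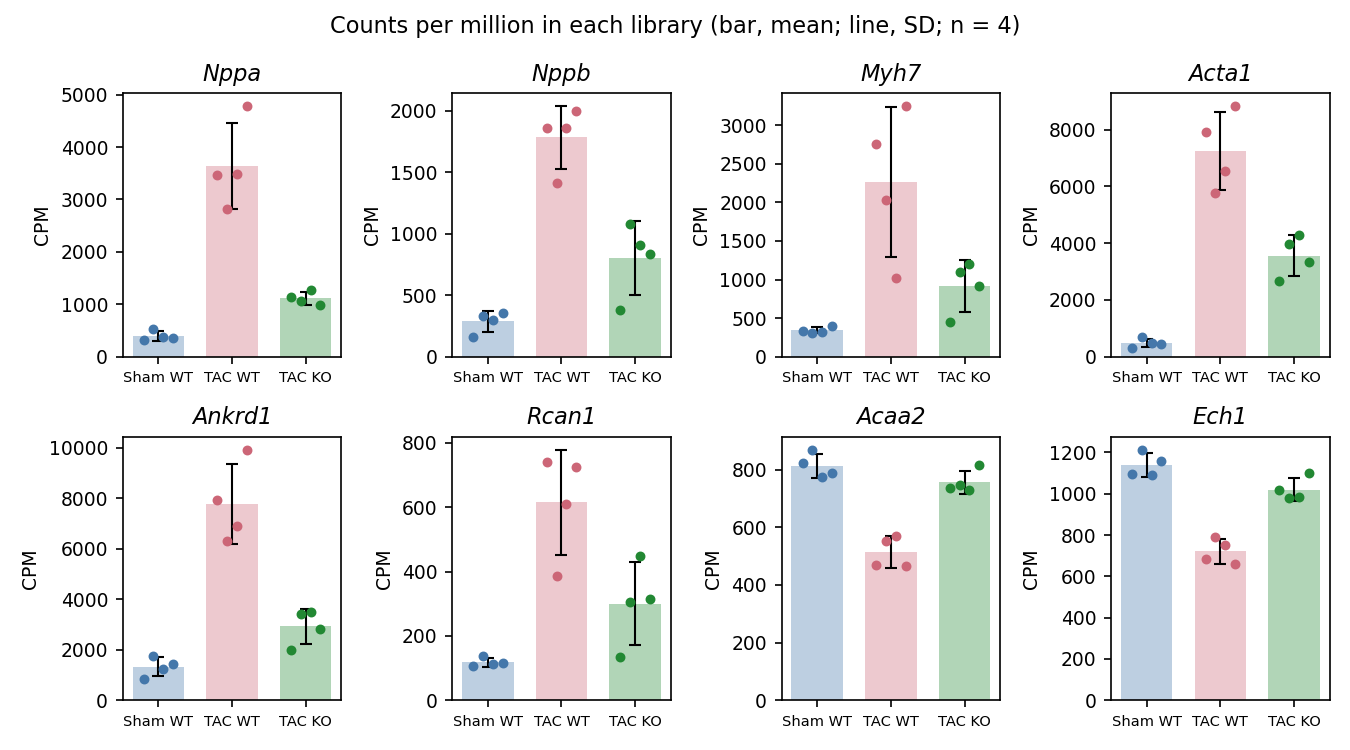
CPM of 8 genes in each of the 12 libraries, with bars at the group mean and lines of 1 SD (n = 4), each axis starting at 0. Nppa averaged 399 CPM in Sham WT, 3639 in TAC WT and 1117 in TAC KO, and Acaa2 averaged 815, 515 and 757 CPM.

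The comparison of TAC KO with TAC WT asked how the knockout hearts differed under the same surgery. Nron itself had 0 counts in all 12 libraries, in both of its annotated records. The longer record, ENSMUSG00000086484.1, has 8 exons on chromosome 2 from 33805816 to 33813591 of GRCm38, within the Mvb12b gene, and the other, ENSMUSG00000089596.1, runs from 33812957 to 33813326. A count of 0 allowed up to 0.083 to 0.114 CPM per library, so neither the presence of Nron in wild-type hearts nor its loss in the knockout was seen in these counts. Nron lies on the strand opposite to Mvb12b, and as the strand setting of the counting was not given in the sources used here, a 0 may reflect how reads were assigned and not its level.

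Nppa was lower in TAC KO, at 1117 ± 126 CPM against 3639 ± 823 in TAC WT (log2 -1.70, SE 0.17, edgeR adjusted p = 1.958e-05). Ankrd1 fell by 1.41, Myh7 by 1.31, Nppb by 1.15, Xirp2 by 1.08, Rcan1 by 1.03 and Acta1 by 1.03. In the other direction, Hadh, an enzyme of fatty acid oxidation, rose by 0.60 and creatine kinase Ckm by 0.65. In all, 5110 genes changed, 2428 up and 2682 down, and 1332 of them by 1.5-fold or more, with a median size of 0.39 on the log2 scale among the changed genes. The libraries also differed by group in a technical measure. The median level of genes in the highest GC quintile minus that in the lowest was 0.104 to 0.429 in TAC KO libraries and -0.149 to -0.041 in wild-type libraries (log2), and the longest minus the shortest quintile gave -0.245 to -0.138 against -0.035 to 0.170. With those trends removed, 4234 genes changed, and 66.3% of the calls above were among them.

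**Figure D3:**
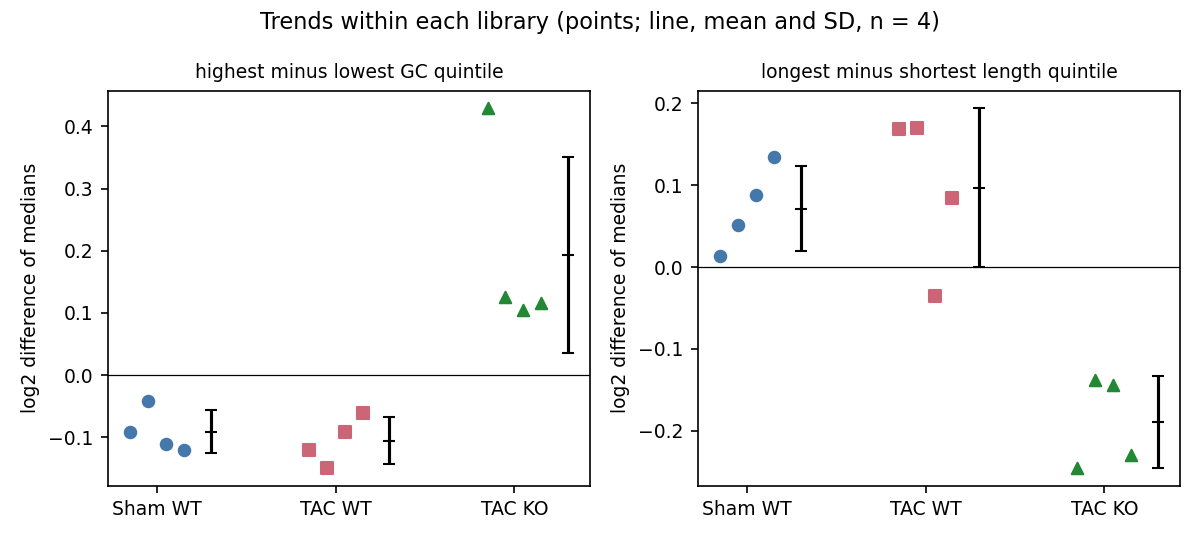
Differences between the median log2 levels of the outer quintiles of genes within each library, by GC content and by transcript length, with the group mean and SD (n = 4). TAC KO libraries ran from 0.104 to 0.429 for GC content, above all wild-type libraries, which ran from -0.149 to -0.041.

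Within the same limits of symbol, level and overlap, the largest named increases were Rab6b (log2 4.11, SE 0.40), Rpl26 (3.71, SE 0.19), Igfals (3.18), the cardiac kinase Tnni3k (2.66, SE 0.10), Scd4 (2.55), Cubn (1.98), Adh1 (1.95) and Cngb3 (1.95). Tnni3k lies on chromosome 3 from 154786291 to 155055407 and rose from 17.3 ± 1.81 to 109 ± 11.4 CPM. The ribosomal protein gene Rpl26 lies on chromosome 11 from 68901583 to 68906989 and rose from 6.23 ± 1.11 to 81.3 ± 20.6 CPM. The largest named decreases within these limits were Eno1b, Syndig1 (-2.51), Hspa1a (-2.25), Nmrk2 (-2.19), Tgfb2 (-1.85), Dok5 (-1.80), Ppm1e (-1.73), Nppa (-1.70), Cd226 (-1.70) and Serpinb1c (-1.66). Eno1b had 2 counts over the TAC KO libraries against 576 in TAC WT, a ratio of 291 with a 95% counting interval of 80.2 to 2410. Adjusted p for these 18 genes ran from 1.14e-09 to 0.0104, and the ranges of the groups did not overlap for any of them, as the naming rule required.

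Of 11 cardiac stress genes, 9 fell and 2 did not pass, with 9 adjusted over the list alone and a median of -1.15. The ranges of the groups overlapped for Myh7, Rcan1, Col8a1, Postn, Col1a1, Atp2a2, Zbtb43, Mvb12b and Gdpd3. No list call in this comparison held with an estimated correlation, and the stress list gave adjusted p = 0.363 with an estimated correlation. Of 26 calcineurin and NFAT pathway genes, 10 fell and 1 rose, or 11 and 1 adjusted over the list alone, with Mef2c at -0.53, Nfat5 at -0.65 and Gsk3b at -0.38. The call of that list gave adjusted p = 0.363 with an estimated correlation and 0.0702 with GC and length trends removed. Of 14 heat shock genes, 9 fell, or 10 adjusted over the list alone, with Hsp90aa1 at -1.16, Dnaja1 at -1.13 and Cryab at -0.45 (adjusted p = 0.363 with an estimated correlation). Of 16 immediate early genes, 6 fell, or 7 adjusted over the list alone, with Egr3 at -1.51, Nr4a1 at -1.29 and Nr4a3 at -1.14 (adjusted p = 0.58 with an estimated correlation), and 10 fell with GC and length trends removed. Of 23 interferon-stimulated genes, 13 fell by both counts, including Ifi44 at -1.06 and Ifit2 at -0.78 (adjusted p = 0.643 with an estimated correlation).

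Of 28 fatty acid oxidation genes, 22 rose, or 23 adjusted over the list alone, with Acaa2 at 0.56 and Eci1 at 0.50 beside Hadh (adjusted p = 0.363 with an estimated correlation). Of 43 nuclear oxidative phosphorylation genes, 30 rose, or 32 adjusted over the list alone, with Sdhd at 0.48 and Sdhb at 0.41 (adjusted p = 0.58 with an estimated correlation). None of 9 mitochondrially encoded mRNAs passed, over all genes or adjusted over the list alone, but with GC and length trends removed 4 rose and camera called the list (adjusted p = 0.00986, and 0.553 with an estimated correlation). With the same trends removed, 21 nuclear oxidative phosphorylation genes and 19 fatty acid oxidation genes rose. Contraction genes moved both ways, with 6 up and 2 down of 24, or 6 and 3 adjusted over the list alone. Triadin Trdn fell by 0.58, and Atp2a2 rose by 0.33 (adjusted p = 0.0455), a call lost on removing any of the TAC KO libraries, TAC WT 3 or TAC WT 4, with adjusted p from 0.0568 to 0.124. Short genes and genes of high GC content were higher in the same TAC KO libraries in which these groups rose.

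Of 44 extracellular matrix genes, 5 fell and 2 rose, or 4 and 1 adjusted over the list alone, and the list was not called (adjusted p = 0.17). Ccn2 fell by 1.65, Tgfb2 by 1.85 and Tgfb3 by 0.83. Col8a1 fell by 0.74, a call lost without TAC KO 1 (adjusted p = 0.0527) or TAC WT 4 (adjusted p = 0.0530). Postn did not pass (log2 -0.48, adjusted p = 0.181), though it passed without TAC WT 2 (adjusted p = 0.0432). Col1a1 was at 246 ± 33.8 CPM in TAC KO and 244 ± 56.8 in TAC WT, a log2 difference of 0.01 (SE 0.15) that did not pass and whose sign turned under some alternatives. Of 14 fibroblast markers, 7 rose by both counts, Scara5 by 0.98, and the list was not called (adjusted p = 0.0576). With GC and length trends removed 4 of them rose.

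Of 19 macrophage markers, 9 rose, or 10 up and 1 down adjusted over the list alone, with C1qb at 0.64, C1qc at 0.53 and Cd68 at 0.69 (adjusted p = 0.643 with an estimated correlation). Of 13 smooth muscle and pericyte markers, 5 rose and 1 fell, or 6 and 1 adjusted over the list alone, with Cnn1 at 1.18, Vtn at 0.85 and Tagln at 0.81. That call gave adjusted p = 0.42 with an estimated correlation and was lost without TAC KO 2 (adjusted p = 0.0549), TAC WT 2 (adjusted p = 0.0757) or TAC WT 4 (adjusted p = 0.0534). It was also lost with GC and length trends removed (adjusted p = 0.0702), when 3 rose and 0 fell. Of 28 ribosomal protein genes, 5 rose, or 4 adjusted over the list alone, with Rpl18 at 0.26. The ribosomal call gave adjusted p = 0.834 with an estimated correlation, 0.0881 without TAC WT 2 and 0.337 with GC and length trends removed. The nuclear RNA Malat1 fell by 1.34, from 2946 ± 247 to 1164 ± 122 CPM, and Neat1 fell by 0.57.

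Of 5 tested protein-coding genes within 500 kb of Nron, adjusted over these genes alone, Zbtb34 (log2 -0.45, adjusted p = 0.00487) and Zbtb43 (-0.31, adjusted p = 0.0172) fell and Mvb12b (0.24, adjusted p = 0.0421) rose. Zbtb34 lies on chromosome 2 from 33406108 to 33431324. Over all tested genes Zbtb34 and Zbtb43 passed and Mvb12b did not (adjusted p = 0.0686). As 33% of all 15477 tested genes passed in this comparison, these calls do not set the neighbours apart from other genes. Mvb12b passed without TAC KO 3 (adjusted p = 0.0270) or TAC WT 2 (adjusted p = 0.0179). Zbtb43 no longer passed over all genes without TAC KO 1, TAC KO 4, TAC WT 2 or TAC WT 4, with adjusted p from 0.0680 to 0.0811. Only 1 neighbour passed adjusted over the neighbours alone without TAC KO 1, TAC KO 4 or TAC WT 4. Among 12 proteins of the complex reported to bind Nron, 1 rose and 4 fell by both counts, with Ppp2r1a at 0.39, and the list was not called (adjusted p = 0.607). With GC and length trends removed the balance turned to 3 up and 1 down.

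**Figure D4:**
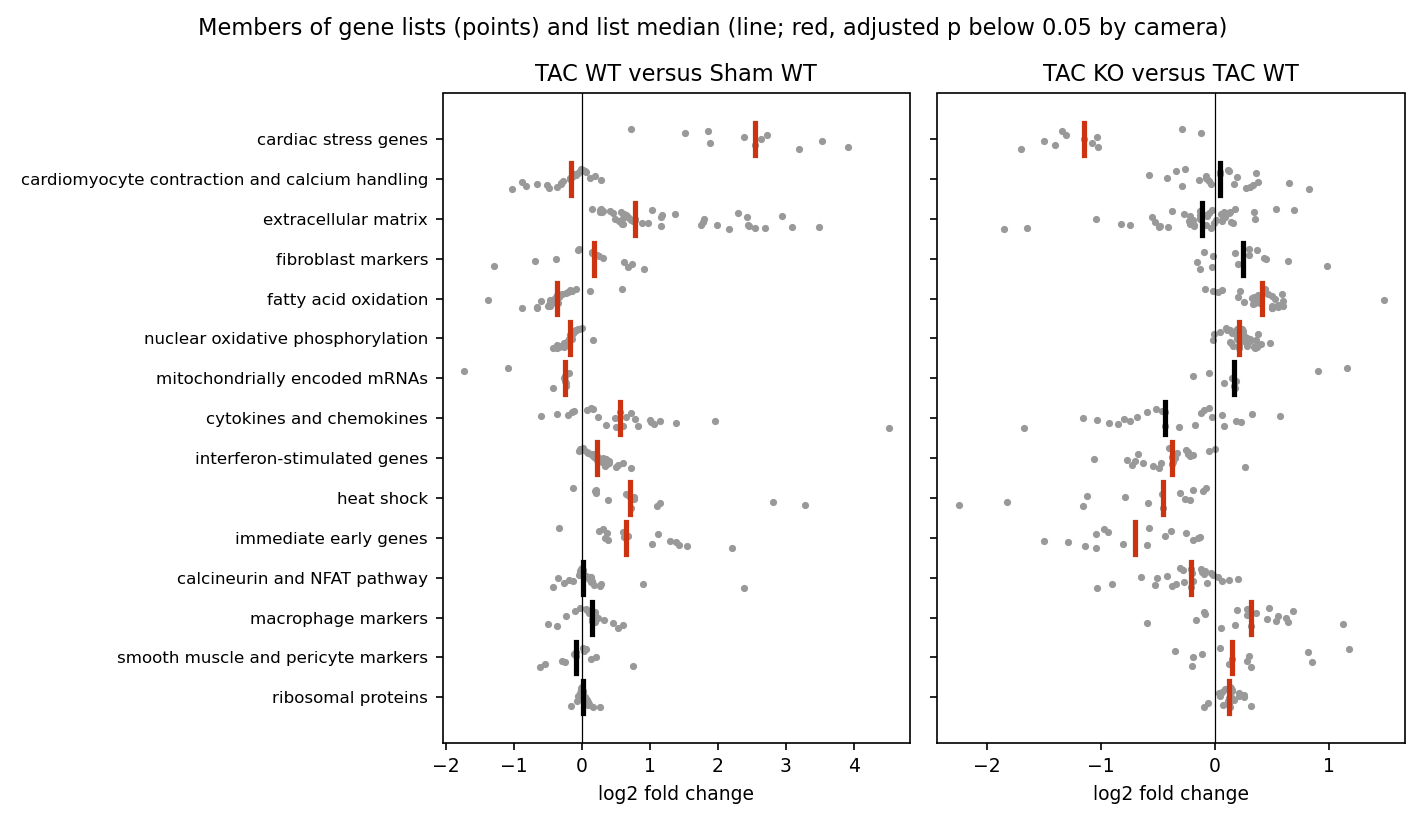
Log2 fold changes of the members (points) of the gene lists called in either comparison, with list medians as lines, in red where camera gave an adjusted p under 0.05. The cardiac stress genes had a median of 2.55 in TAC WT versus Sham WT and -1.15 in TAC KO versus TAC WT.

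The effects of surgery and of the knockout ran against each other across genes. Of the 3051 genes changed in TAC WT versus Sham WT, 84.1% had a knockout effect of opposite sign. As TAC WT enters both, simulated data in which the knockout equalled TAC WT gave 62.2% on average and at most 64.2%, and splits that shared no TAC WT library gave 79% on average (70.6 to 86%). Genes that rose after TAC and fell in TAC KO numbered 660, where independence gives 259.2, among them Nppa, Myh7, Hspa1a, Tgfb2 and Hbegf. Genes that fell after TAC and rose in TAC KO numbered 804, where independence gives 243.9, among them Acaa2 and Angpt1. Only 41 genes rose in both comparisons and 39 fell in both.

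**Figure D5:**
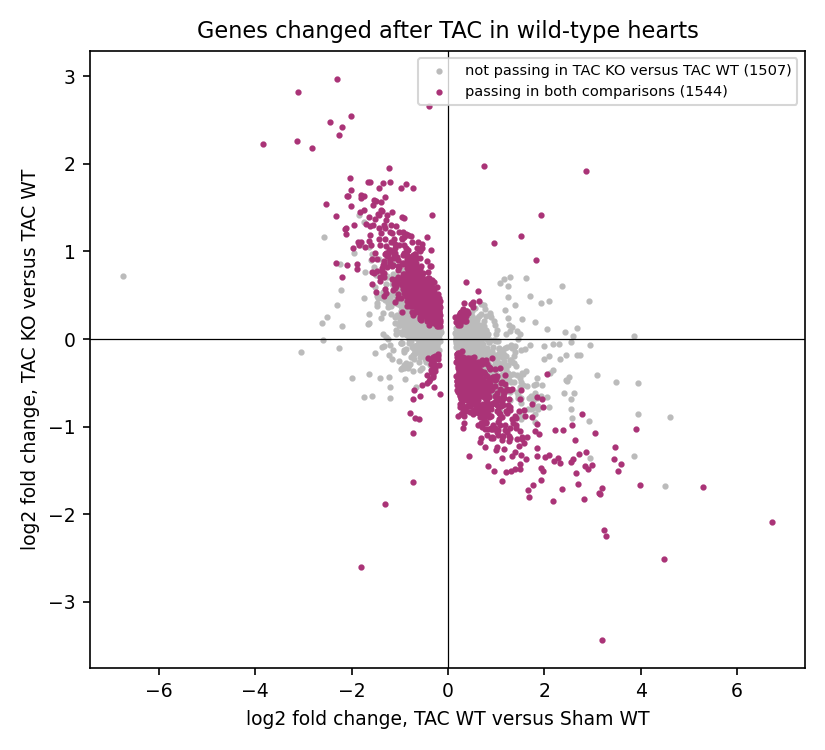
Log2 fold changes of the 3051 genes changed in TAC WT versus Sham WT, with the TAC effect on the horizontal axis and the knockout effect on the vertical axis. Of these genes, 1544 also passed in TAC KO versus TAC WT and 1507 did not.

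The comparison of TAC KO with Sham WT combined surgery and genotype, since no sham-operated knockout hearts were analysed here. Nppa stayed higher than in Sham WT, at 1117 ± 126 against 399 ± 93.2 CPM (log2 1.49, SE 0.17, edgeR adjusted p = 6.376e-05), and Acta1 rose by 2.88. The matrix genes Cilp (2.51) and Ltbp2 (2.68) rose, as did Mfap5 (1.39) and Gdf15 (2.02). In all, 4273 genes changed, 1986 up and 2287 down, and 1172 by 1.5-fold or more. With GC and length trends removed, 3430 genes changed, and 63.2% of the calls above were among them.

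Within those limits, the highest named changes were Sprr1a (log2 3.73), Rpl26 (3.64), Ankrd2 (3.44) and Rab6b (3.34), and the lowest were Eno1b, Sbk3 (-2.61), Scn10a (-2.43), Cntn2 (-2.36) and Cenpf (-2.25). Eno1b had 2 counts in TAC KO against 559 in Sham WT, a ratio of 274 with a 95% counting interval of 75.5 to 2270. The ranks of Sprr1a and Ankrd2 rested on TAC KO 3, without which both lay below Rpl26 and Rab6b, with Ankrd2 at a log2 change of 2.73 and Sprr1a lower still. The call of Sprr1a was lost without TAC KO 3 (adjusted p = 0.0595), and that of Ankrd2 without TAC KO 3 (adjusted p = 0.0599), Sham WT 2 (adjusted p = 0.0523) or Sham WT 4 (adjusted p = 0.0533). Sbk3, Scn10a, Cntn2 and Cenpf had also fallen in TAC WT versus Sham WT. Genes that rose in both TAC groups against Sham WT numbered 653, where independence gives 192, and 524 fell in both, where independence gives 229.8. As Sham WT enters both, comparisons that gave each TAC group its own 2 Sham WT libraries found 461 such genes on average, with fewer libraries in each fit. Simulated data with no group difference gave 0. With no true changes to call, they cannot show how far a shared Sham WT raises the overlap. Across genes the 2 effects correlated at 0.53, against 0.501 on average in these simulations and 0.416 on average in those split comparisons.

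Of 11 cardiac stress genes, 10 rose by both counts with a median of 1.39 (adjusted p = 0.297 with an estimated correlation). Of 44 matrix genes, 33 rose, or 37 up and 1 down adjusted over the list alone (adjusted p = 0.387 with an estimated correlation). Of 14 fibroblast markers, 9 rose by both counts, including Lum at 0.95 and Mgp at 0.79 (adjusted p = 0.297 with an estimated correlation). Of 19 macrophage markers, 11 rose by both counts, with C1qb at 0.84 and C1qc at 0.69 (adjusted p = 0.805 with an estimated correlation). Of 26 calcineurin and NFAT pathway genes, 9 fell and 2 rose, or 9 and 3 adjusted over the list alone, with Mef2a at -0.64 and Nfat5 at -0.53 (adjusted p = 0.613 with an estimated correlation). Of 28 ribosomal protein genes, 9 rose, or 10 adjusted over the list alone, with Rpl18 at 0.30 (adjusted p = 0.921 with an estimated correlation). Of 28 fatty acid oxidation genes, 2 rose and 1 fell, or 1 and 1 adjusted over the list alone, with a median of 0.01. The GC and length trends of TAC KO libraries differed from Sham WT as they did from TAC WT.

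Many genes set TAC KO apart from both wild-type groups. In the same direction against both, 893 genes were higher and 1366 lower, and 2070 of these 2259 had not passed in TAC WT versus Sham WT. GC and length trends also set the TAC KO libraries apart from both wild-type groups. Removing them kept 66.3% of the calls against TAC WT and 63.2% of those against Sham WT. The count of 2259 was not recomputed without these trends. At 4-fold or more against both groups there were 22 genes, 9 higher and 13 lower, including Rab6b, Rpl26, Igfals and Tnni3k. Of the 22 genes, 6 were pseudogenes, and the ranges of TAC KO and TAC WT overlapped for Gdpd3, Cyp1a1 and Capn11. Some were of low level, such as Gm13534 at 0.313 CPM in TAC WT and 0 in TAC KO. Capn11, at 1.47 ± 1.95 CPM in TAC WT, also varied widely within that group. E330017L17Rik had 196 counts over the TAC KO libraries and 0 in TAC WT, at least 64.6-fold higher against a limit of 3 counts over the group. Rpl26 had 1771 to 3289 counts in TAC KO libraries and 174 to 265 in wild-type libraries. Its processed pseudogene Gm15772 matched it at 95% identity or more. Gm15772 had 2 to 3 counts in TAC KO 1 to 3 and 859 in TAC KO 4, against 1137 to 1636 in wild-type libraries. Gdpd3 had 1111 and 835 counts in TAC KO 1 and TAC KO 4 and 33 and 42 in TAC KO 2 and TAC KO 3.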

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

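The test of the cardiomyocyte share was chosen only after the result was seen, and so was the removal of GC and length trends as a setting. The tests of the other explanations were fixed before their results were seen.

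In groups of 4 libraries, a library was singled out when its gap to the nearest other library took up most of the group's range, by Dixon's ratio at the 5% level. Chance does this in about 1 of 20 groups, and 30 of 348 groups met the limit where chance gives 17.4, in genes that were not drawn at random. Sham WT 4 had 27596898 counts against 34382907 to 35491024 in the other libraries of its group. TAC KO 1 had a GC difference of 0.429, the highest of its group, in which the lowest was 0.104. In TAC WT 4, Ankrd2 was at 14.5 CPM, Cd226 at 3.05, Osmr at 66.7 and Igfals at 0.257. In TAC WT 3, Hsp90aa1 was at 264 CPM, Flt1 at 266 and Ankrd63 at 0.0886. In TAC WT 2, Adh1 was at 5.36 CPM, Cd14 at 4.40 and Lum at 47.4, and in TAC WT 1 Zbtb34 was at 8.20. In TAC KO 3, Sprr1a was at 3.36 CPM, Egr3 at 5.42 and Tagln at 93.5, while Trdn was at 254 in TAC KO 1. In TAC KO 4, Rpl26 was at 50.7 CPM and Gm15772 at 24.6. Among Sham WT libraries, Cilp was at 13.6 CPM, Igfals at 0.892 and Pln at 5958 in Sham WT 1, Lrp8 at 1.37 and Gm4735 at 1.17 in Sham WT 3, and Dnaja1 at 46.6 in Sham WT 4.

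Some listed genes were too unevenly counted to be tested. The mitochondrial mRNA mt-Co3 had 8385 counts in TAC WT 4 against 3 to 1000 in the other libraries of the group, and 193 in TAC KO 4 against 0 to 2. The club cell gene Scgb1a1 had 137 counts in TAC KO 1 and 0 in the other TAC KO libraries, and 1 in Sham WT 1. The fast skeletal myosin Myh4 had 210 counts in TAC WT 4 against 0 to 3.

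Regrouping of the libraries argues against chance as the source of the gene counts. In fits of the 8 libraries of each comparison, 1 of 35 splits, the real one, called as many genes. It called 3295 in TAC WT versus Sham WT, 4019 in TAC KO versus TAC WT and 4538 in TAC KO versus Sham WT, and the highest other split called 1 in each.

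The first pattern was the number of genes of small fold change between TAC KO and TAC WT. Removing GC and length trends left 82.9% as many calls, which argues against these trends as the whole cause, although 66.3% of the original calls were among them. The nuclear-retained RNAs tested other than Malat1 were Kcnq1ot1, Rian, Meg3, Neat1, Mirg, Airn, Peg13, Firre and Tug1. They had a median log2 change of -0.53, with quartiles of -0.63 and -0.28, and 7 of 9 fell and none rose. The median was the value of Mirg, at 0.766 CPM in TAC WT, which did not pass (edgeR adjusted p = 0.222). That median met the bound of -0.5 set for less nuclear RNA in the TAC KO preparations. That explanation therefore stays open, and it may share its genes with the GC and length trends. A genotype effect, an unlabelled difference in library preparation and a difference in the surgery were not tested, and group membership carries all of them.

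The second pattern was the 22 genes that differed by 4-fold or more between TAC KO and both wild-type groups, some of them with overlapping ranges. None lay within 20 Mb of Nron (0.0%), which argues against DNA carried along with the deletion within that distance. Gm13534, Gm4735 and Gm13886 lay farther along chromosome 2, starting at 58108060, 80837141 and 104820179. A longer carried segment was not tested. The number within 5 Mb of another was 0, below the bound set beforehand, the median of 2 in random draws. As few were found in 27.2% of draws. The test sees only segments that hold several of these genes, and scattered segments would escape it. It therefore cannot decide on other segments of different descent, and that explanation stays open. A near-identical copy was found for 31.8% of the 22 genes and for 5.7% of 1000 random genes, between the bounds set. Shared reads may therefore account for part of the pattern, as in Rpl26 and Gm15772. The sum of those 2 genes ran from 2553 to 3292 counts in TAC KO libraries and 1311 to 1860 in wild-type libraries. Moving reads between these 2 genes alone would not make that difference. Rpl26 also had a copy in Gm8253, and how reads matching several genes were counted was not given. The sum therefore cannot exclude shared reads as the whole source of the difference at Rpl26.

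The third pattern was that genes changed by surgery in wild-type hearts moved the other way in TAC KO. The opposing share was 79.0% when no TAC WT library entered both effects, and the stress genes kept a median log2 change of -1.22 with GC and length trends removed, which argues against both technical sources as the whole cause. Contraction and calcium handling genes had a median of 0.04 (SD 0.33, n = 24 genes) against -1.15 for the stress genes. That argues against a lower share of cardiomyocytes as the whole source of the stress gene fall. It cannot exclude a smaller loss, because the contraction list itself moved after TAC in wild-type hearts (median -0.16). In TAC KO versus TAC WT, 9 macrophage and 7 fibroblast markers rose, while 3 endothelial markers fell. A weaker response to pressure in the knockout is a candidate explanation, and so is a milder constriction in those mice, which was not tested. Without sham-operated knockout hearts, and with less nuclear RNA open for the same libraries, the data do not separate these.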

How the results depend on the processing

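The removal of GC and length trends, and every alternative for the neighbours of Nron, were chosen only after the data were seen. The other alternatives were fixed before the data were examined. No paired analysis was possible because the labels carry only library numbers, and replicate numbers were given in accession order. A sex covariate was not run because all libraries had Y-linked counts and at most 9 Xist counts.

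Counts of changed genes in all 3 comparisons stayed within 1.5 times the reported number under both other count models, both other scalings, both filters, fits of the compared groups alone and GC and length offsets. In TAC WT versus Sham WT, 1 surrogate variable gave 1526 genes. The 1.5-fold minimum, which by its construction keeps fewer genes, gave 1248, 1332 and 1172. The opposing share was 82% with 1 surrogate variable. With an estimated correlation, 1 list was called in TAC WT versus Sham WT and 0 in TAC KO versus TAC WT, and 1 surrogate variable left 1 neighbour of Nron. The cause was not tested.

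Leaving out each library in turn gave 2251 to 3474, 3963 to 5080 and 3070 to 3851 changed genes in the 3 comparisons, an opposing share of 82.1 to 86.6%, 9 to 15 and 9 to 13 lists, and 1 to 3 neighbours of Nron. That last count was 1 without TAC KO 1, TAC KO 4 or TAC WT 4. Col1a1 in TAC KO versus TAC WT turned sign, to -0.095 with voom and -0.048 with GC and length offsets, and ran from -0.104 to 0.141 with a library left out, below 0 without TAC KO 2, TAC KO 3, TAC WT 2 or TAC WT 3. It passed in none of these.

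Among the 150 gene results examined, 50 values fell short of the threshold under an alternative, 4 came to pass, and 6 turned sign, all of these in Col1a1. These genes were chosen after values had been seen. Over all 425 results the naming rule allowed, 283 of 7191 values fell short, 127 came to pass and 91 turned sign, none of them passing in both. Calls of mt-Co1, Cd14, Osmr, Ankrd2, Atp2a2 and Tnnt3 in TAC WT versus Sham WT were lost with 1 surrogate variable, with adjusted p from 0.0760 to 0.318. In TAC KO versus TAC WT the same setting lost Col8a1 (0.0584), Atp2a2 (0.152), Zbtb43 (0.0767), Gm15772 (0.0589) and Gdpd3 (0.0523), and voom lost Gdpd3 (0.190) and Zbtb43 (0.0528). Fits of the compared groups alone lost Atp2a2 (0.0919), Zbtb43 (0.0627) and Gm15772 (0.0713) there and mt-Co1 (0.0783) in TAC WT versus Sham WT, and mt-Co1 was also lost with no filter (0.114) and with GC and length offsets (0.0502). Upper-quartile scaling gained Mvb12b (0.0422). Gm15772 lost its call without TAC KO 1 (adjusted p = 0.0573). List calls lost with a library left out were fibroblast markers (without Sham WT 1, 2 or 3 or TAC WT 1 or 3, adjusted p 0.0539 to 0.277), mitochondrial mRNAs (without Sham WT 2, 0.0915, or Sham WT 3, 0.0679), cytokines (without Sham WT 1, 0.0539, or TAC WT 4, 0.0796) and interferon-stimulated genes (without TAC WT 3, 0.268) in TAC WT versus Sham WT. In TAC KO versus TAC WT they were smooth muscle and pericyte markers (without TAC KO 2, 0.0549, TAC WT 2, 0.0757, or TAC WT 4, 0.0534) and ribosomal proteins (without TAC WT 2, 0.0881). RLE scaling (0.0511) and GC and length offsets (0.0513) also lost the fibroblast list. In TAC KO versus TAC WT the offsets lost the calcineurin and NFAT (0.0702), smooth muscle (0.0702) and ribosomal (0.337) lists and gained mitochondrial mRNAs (0.00986) and endothelial markers (0.0164). With fry, cytokines (0.122) and interferon-stimulated genes (0.132) in TAC WT versus Sham WT were lost, as were ribosomal proteins in TAC KO versus TAC WT. Fry gained angiogenic and growth factors in TAC WT versus Sham WT (0.0369) and in TAC KO versus TAC WT (0.00134). It also gained fibroblast markers (0.0264) and sex-linked genes (0.0264) in TAC KO versus TAC WT. The median log2 change of all genes lay between -0.005 and 0.024 under the 3 scalings, and upper-quartile scaling turned the share of rising genes in TAC KO versus TAC WT from 47.5 to 53.8%. Nron had 0 counts in each library, and depth and read assignment were not told apart.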

Other observations

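Growth factor genes changed in both directions after TAC in wild-type hearts. Of 30 angiogenic and growth factor genes, 10 rose and 6 fell, or 10 and 7 adjusted over the list alone. Hbegf rose by 1.94 on the log2 scale and Frzb by 1.85, while Angpt1 fell by 2.13. In TAC KO versus TAC WT, 3 rose and 6 fell by both counts, with Vegfa at -0.83, Hbegf at -1.48 and Angpt1 at 1.26. Camera called this list in no comparison. Of 15 endothelial markers, 3 fell in TAC KO versus TAC WT by both counts, the receptors Flt1 (-0.75) and Kdr (-0.62) among them, and the list was not called (adjusted p = 0.0512). With GC and length trends removed 5 fell and the list was called (adjusted p = 0.0164, and 0.736 with an estimated correlation). Of 21 glycolysis genes, 4 rose and 5 fell after TAC in wild-type hearts, or 5 and 5 adjusted over the list alone, with Pfkp at 1.13 and Pfkfb1 at -2.19. In TAC KO versus TAC WT, 9 rose and 2 fell, or 10 and 3 adjusted over the list alone, but 3 rose and 3 fell with GC and length trends removed. Mef2a, of the calcineurin and NFAT list, fell by 0.42 in TAC WT versus Sham WT, where 3 of that list rose and 1 fell, or 2 and 1 adjusted over the list alone.

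Of 26 cell cycle genes, 1 rose after TAC and none adjusted over the list alone, while in TAC KO versus TAC WT 1 rose and 2 fell by both counts, with Ccnd1 at -0.99. Of 4 tested skeletal muscle markers, Tnnt3 alone passed after TAC (log2 1.77), by both counts. It was highest in TAC WT 4, at 4.12 CPM against 0.902, 0.862 and 1.595 in the other TAC WT libraries, and its log2 change was 1.07 without that library, which also held the counts of Myh4. With 1 surrogate variable Tnnt3 was at 0.96 and its call was lost (adjusted p = 0.253). Of 19 tested ER stress genes, 4 rose after TAC by both counts, and in TAC KO versus TAC WT 2 rose and 3 fell. Of 16 clock genes, 3 fell after TAC by both counts. No member of the erythroid or neutrophil lists passed in any comparison, and of 9 lymphocyte markers 1 rose in TAC KO versus TAC WT. The median, mean and test of a list differed in sign for glycolysis, atrial markers and sex-linked genes in TAC WT versus Sham WT, for cell cycle and ER stress in TAC KO versus TAC WT, and for lymphocyte, angiogenic, clock and epicardial lists in TAC KO versus Sham WT.

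The pseudogene Gm4735, chosen after its values were seen, had 0 to 2 counts in TAC KO libraries and 41 to 65 in wild-type libraries. Gm4735 matched a transcript of Eno1, and Eno1b a transcript of Gm5855, each at 95% identity or more. The closest copy found for each, in any other gene, was 99.8% identical. Rpl26 took 99.9% of the summed counts of Rpl26 and Gm15772 in TAC KO 1 to 3, 67.3% in TAC KO 4 and 10.5 to 15.3% in wild-type libraries.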
